A study of Homo sapiens with 6 samples.

How the data were processed

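Gene expression was measured in U-87 glioma cells on 6 Affymetrix arrays, 3 labelled P68 knockdown and 3 labelled P68 wild type. The labels' treatment note names transfection with an siRNA against P68 or with a reagent abbreviated NC, and it does not tie NC to the wild-type arrays by name. The platform named in the probe annotation is the Affymetrix Human Gene 1.0 ST array, whose probe sets summarise probes along a transcript. The deposited table holds log2 signals rounded to 2 decimals, and RMA was used to make them, per the submitters' processing notes. RMA corrects the background, equalises the distribution of probe signals over the arrays and summarises the probes of each probe set, so a change shared by most genes would not be visible in these values. The RMA software, its version and any filter are not given in the sources used here. The range and quartiles of the values were checked and match a log2 scale. The table held 29096 probe sets, no missing value and no Affymetrix control probe set by name, so RNA quality was not compared through control probe sets. Detection calls were not used here, so a low signal cannot be told from background.

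The probe annotation paired 19460 probe sets with 1 gene symbol, 1754 with several and 7882 with none. Of the 19460, 19429 matched a gene of the reference table (GRCh38.p14) by gene identifier, and 0 symbols differed. No genome build is stated for the array values, so no coordinates are given. For each of the 18417 genes, the probe set with the highest mean over the 6 arrays was kept. Of these genes, 769 had more than 1 probe set. Genes with close copies, such as ribosomal protein genes with pseudogenes and clustered small nucleolar RNAs, can share probe signal.

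Knockdown and wild type were compared on all 18417 genes with limma 3.58.1 (lmFit and eBayes, two-sided) in R 4.3.3, with group as the only term and no filter on dim probe sets. P-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. The design, the alternatives and 30 gene lists were fixed before the data were examined. The lists hold 695 genes, of which 638 were measured. Lists were tested with camera (limma) at the preset inter-gene correlation of 0.01, adjusted over the 30 lists, and again with the correlation estimated from the arrays. The adjustment over DDX5, DDX17 and DUSP5 alone was chosen after the data were seen. The genes named are DDX5, DDX17 and DUSP5, and the 10 genes with the largest rise and the 10 with the largest fall among those past the threshold whose groups did not overlap and whose brighter group mean was at or above the median gene. XIST, Y-linked genes and unnamed reading frames were left out of these. Also named are up to 4 members of each list past the threshold or, where none passed, the member with the largest absolute difference. No gene passed the threshold, so each list is represented by that member. Further members given with the lists of lower median, and the genes of at least a 2-fold difference, were chosen after their values were seen.

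The fit was tested on simulated data drawn from the wild-type means and moderated variances of the 18417 genes in 20 sets, each with 200 genes changed by known amounts. On average 6.8% of the calls in these sets were false. A list of 32 genes shifted by 0.1 was called by camera in 85% of the sets, and 0.34% of unshifted lists were called. These simulated genes were independent of each other. The number of arrays limits the precision, with a median standard error of 0.12 on the log2 difference.

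No array was a copy of another: the SD of the difference between 2 arrays over all probe sets was 0.22 at least. The alternatives were centring on the array median, repeated quantile normalisation, cyclic loess, leaving out the dimmest 40% of genes, the mean over a gene's probe sets, every probe set tested on its own, an intensity trend with robust estimation, array weights, a replicate block, a threshold of 0.01 and leaving out each array in turn. Leaving out probe sets prone to cross-hybridisation by their name ending was not run, since 0 probe sets carried that ending.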

Results

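The study asked how lowering P68 alters gene expression in glioma cells, and its title ties P68 to DUSP5, growth and invasion. P68 is the DEAD-box RNA helicase encoded by DDX5, which takes part in transcription, splicing and microRNA processing. U-87 is an established human glioma cell line. Total RNA was hybridised to 6 Affymetrix gene-level arrays, 3 labelled P68 knockdown and 3 labelled P68 wild type. The signals of 29096 probe sets ran from 1.22 to 13.81 on the log2 scale, and the array medians lay between 4.32 and 4.37. The labels do not say whether the arrays of a group came from separate cultures, so the p-values measure the spread between these arrays, which may be technical. Over all probe sets, pairs of wild-type arrays correlated with r = 0.987 to 0.990, and pairs of knockdown arrays with r = 0.979 to 0.986. Pairs that crossed the groups correlated with r = 0.980 to 0.991, and the closest pair of all was knockdown replicate 3 with wild-type replicate 3.

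DDX5, the targeted gene, was lower on all 3 knockdown arrays than on any wild-type array. Its signal was 9.47, 9.79 and 9.91 in knockdown replicates 1, 2 and 3, against 10.09, 10.25 and 10.30 in the wild type. The group means were 9.72 ± 0.23 and 10.21 ± 0.11 (SD, n = 3 each), a log2 difference of -0.49 ± 0.13 (SE). The DDX5 signal of the knockdown was 71.2% of that of the wild type, with a 95% confidence interval of 58.4% to 86.9%. DUSP5, a nuclear phosphatase that inactivates ERK, was higher on all 3 knockdown arrays, at 5.73 ± 0.10 against 5.35 ± 0.08 (SD, n = 3 each). Its log2 difference was 0.39 ± 0.10 (SE), or 131% of the wild-type signal with a 95% confidence interval of 112% to 153%. DDX17, the closest paralog of DDX5, gave 8.06 ± 0.51 in the knockdown and 7.92 ± 0.21 in the wild type (SD, n = 3 each). Its log2 difference of 0.14 ± 0.22 (SE) became -0.15 without knockdown replicate 1 and 0.34 without knockdown replicate 2.

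These 3 genes were fixed in advance, while the adjustment over them alone was chosen after the data were seen. In it, DDX5 and DUSP5 each had an adjusted p = 0.0054 by limma when adjusted over the list alone, and DDX17 had an adjusted p = 0.546. DUSP5 is named in the study's title, so its place on this list is not independent evidence. Adjusted over all genes tested, both had an adjusted p of 0.902. In an exact permutation test (two-sided) DDX5 and DUSP5 reached p = 0.1, the smallest value that 3 arrays against 3 allow.

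**Figure D1:**
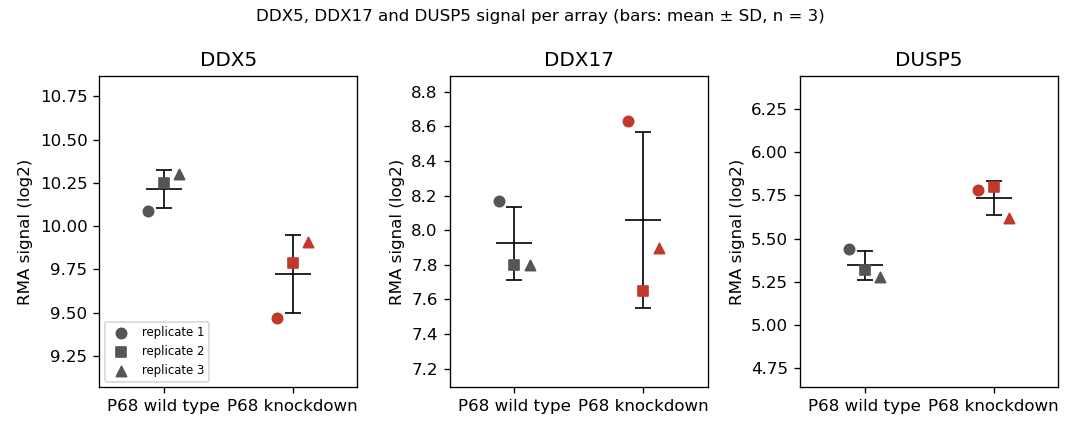
RMA signal (log2, vertical axis) of DDX5, DDX17 and DUSP5 on each array of the P68 wild-type and knockdown groups, with symbols for the replicate number and bars for the mean ± SD (n = 3). DDX5 lies between 9.47 and 9.91 in the knockdown, below the lowest wild-type value of 10.09, and DUSP5 lies between 5.62 and 5.80, above the highest wild-type value of 5.44.

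Across the 18417 genes tested, none differed between knockdown and wild-type arrays at an adjusted p under 0.05 in limma. Unadjusted p-values under 0.05 were found for 937 genes, 557 higher and 380 lower in the knockdown, against 920.85 expected if no gene differed. With each array centred on its median, the same count was 443 higher and 484 lower. The 2 groups did not overlap for 1866 genes, 10.1% of those tested, where chance gives 10%. The absolute log2 difference had a median of 0.09 and was under 0.25 for 92.1% of genes. Of all genes tested, 2 reached a 2-fold difference, and both were chosen after their values were seen. Both were among the dimmest 40% of genes by mean signal, where signal cannot be told from background here. OR2T8, an olfactory receptor gene, was 4.53 ± 0.22 in the knockdown and 3.51 ± 0.21 in the wild type (SD, n = 3 each), a log2 difference of 1.02 ± 0.14 (SE) with an adjusted p of 0.487, the smallest of all genes. ADCY10P1, an adenylate cyclase pseudogene, was 2.39 ± 0.36 against 3.58 ± 1.05 (SD, n = 3 each), with wild-type replicate 2 at 4.79 and the other two at 2.99 and 2.96, and the log2 difference of -1.19 became -0.58 without wild-type replicate 2.

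The size of change that 3 arrays per group can show was tested on simulated data. The simulated arrays were drawn at the moderated variances of these 18417 genes, which vary less between genes than the measured variances, so the shares recovered hold for that spread only. With 200 genes changed in 3 arrays against 3, limma recovered 99.5% of genes changed 2-fold and 52% of genes changed 1.41-fold. These 200 were 50 each at 1.41-, 2-, 2.83- and 4-fold, and calls among the larger changes ease the adjusted threshold for the smaller ones. The 52% thus holds only beside that many large changes, which the measured data did not show. For a gene changed on its own, a 2.1-fold difference would be needed at the median standard error of 0.12. A gene changed on its own by less was thus not reliably detectable at that standard error.

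**Figure D2:**
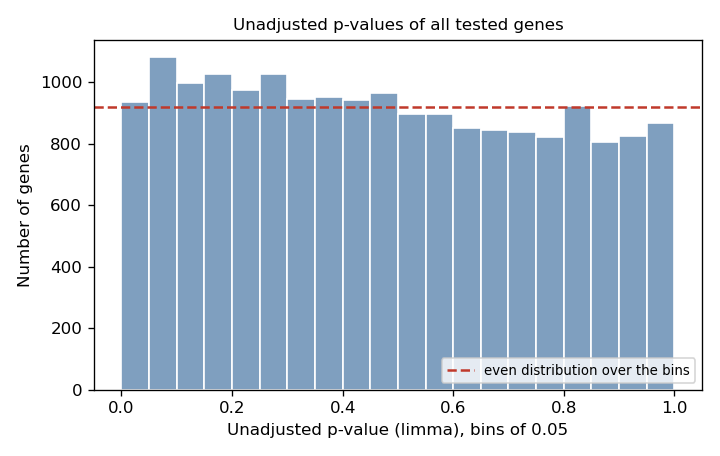
Number of genes (vertical axis) in each bin of unadjusted limma p-values (horizontal axis) for the 18417 genes tested. The first bin holds 937 genes, beside the 920.85 per bin of an even distribution drawn as the dashed line. The bins from 0.05 to 0.5 lie above that line, at 941 to 1083 genes.

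The gene groups around ERK signalling did not pass the threshold as lists. Of 17 dual-specificity phosphatase and ERK feedback genes, 9 had values above 0 and 8 below, with a median log2 difference of 0.003 (adjusted p = 0.935, camera). DUSP5 had the largest difference of this list, with an adjusted p of 0.062 over the list alone. Of 23 early response genes driven by ERK, 13 lay above 0 and 10 below (median 0.03, adjusted p = 0.935, camera). IER2, an immediate early gene, differed most, at 5.83 ± 0.04 in the knockdown and 5.46 ± 0.24 in the wild type (SD, n = 3 each). Of 23 glioma and growth factor signalling genes, 15 lay above 0 (median 0.03, adjusted p = 0.935, camera), led by IGFBP2, a secreted binder of insulin-like growth factors, at 0.37 ± 0.13 (log2 difference ± SE). With single arrays left out the medians ran from -0.045 (without wild-type replicate 1) to 0.06 (without wild-type replicate 3) for the phosphatases, from -0.04 (without wild-type replicate 1) to 0.04 (without wild-type replicate 3) for the early response genes and from -0.02 (without knockdown replicate 3) to 0.09 (without wild-type replicate 1) for the glioma list. No member of these 3 lists passed the threshold over all genes or over its list alone.

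In all, 7 gene lists lay lower in the knockdown by camera with its preset correlation, by medians of 0.04 to 0.09 on the log2 scale, and none lay higher. With the correlation between genes estimated from the arrays, all 7 calls were lost (adjusted p = 0.669 for each). Of 32 genes of the G1/S transition and DNA replication, 23 had values below 0 (median -0.09, adjusted p = 0.0116, camera). POLE2, a subunit of DNA polymerase epsilon, gave -0.34 ± 0.21 (SE), PRIM1, the primase catalytic subunit, gave -0.32, and MCM7 of the replicative helicase gave 0.24 (the latter pair chosen after their values were seen). Of 31 genes of G2/M and mitosis, 20 lay below 0 (median -0.04, adjusted p = 0.0228, camera), with -0.39 ± 0.18 (SE) for the kinesin KIF2C, -0.35 for CDK1, and 0.15 for the proliferation marker MKI67 (the latter pair also chosen after their values were seen). Of 15 partners of P68 in microRNA processing and RNA binding, including DDX17, 14 lay below 0 (median -0.09, adjusted p = 0.0116, camera), with DDX1 at -0.44 ± 0.16 (SE). Of 36 splicing factors, 27 lay below 0 (median -0.08, adjusted p = 0.0145, camera), with PTBP2 at -0.27 ± 0.13 (SE). Of 39 ribosomal protein genes, 25 lay below 0 (median -0.07, adjusted p = 0.0145, camera), with RPL24 at -0.52 ± 0.18 (SE). Of 27 ribosome biogenesis genes, 19 lay below 0 (median -0.06, adjusted p = 0.0291, camera), with NOLC1 at -0.32 ± 0.21 (SE). Of 31 oxidative phosphorylation genes, 23 lay below 0 (median -0.07, adjusted p = 0.0158, camera), with the cytochrome c oxidase subunit COX5B at -0.51 ± 0.15 (SE).

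No member of these 7 lists passed the threshold over all genes or over its list alone. All 7 calls were lost without knockdown replicate 2 (adjusted p = 0.311 to 0.632, camera), which had the lowest median of the 3 knockdown arrays in each list, whereas 5 were kept without knockdown replicate 1 or 3 or wild-type replicate 2 or 3, and 3 without wild-type replicate 1. The medians moved with single arrays. Without knockdown replicate 2 the ribosomal protein median was -0.002, and the others were -0.07 for P68 partners and for ribosome biogenesis, -0.065 for splicing, -0.05 for G1/S and for oxidative phosphorylation and -0.03 for G2/M. The members moved as well: without knockdown replicate 2 POLE2 gave -0.12, PRIM1 -0.19, DDX1 -0.28 and RPL24 -0.31, and without knockdown replicate 1 NOLC1 gave -0.11, PTBP2 -0.18, MCM7 0.14 and MKI67 0.07. KIF2C gave -0.18 and MKI67 0.29 without wild-type replicate 1, NOLC1 -0.10 without wild-type replicate 2, POLE2 -0.59 without knockdown replicate 3 and -0.22 with array weights, and MKI67 -0.007 without wild-type replicate 3. Without wild-type replicate 1 the median was 0.005 for G2/M (adjusted p = 0.351, camera), -0.01 for oxidative phosphorylation, -0.05 for G1/S and -0.14 for ribosome biogenesis. Without knockdown replicate 1 it was -0.15 for P68 partners, -0.12 for G2/M and for oxidative phosphorylation and -0.105 for ribosomal proteins. Without knockdown replicate 3 it was -0.05 for G1/S, -0.04 for oxidative phosphorylation and -0.10 for ribosome biogenesis. Without wild-type replicate 2 it was -0.03 for ribosome biogenesis, -0.04 for splicing and -0.08 for G2/M, and without wild-type replicate 3 it was -0.10 for G2/M and -0.11 for oxidative phosphorylation. With the dimmest 40% of genes left out 4 of the 7 were kept, and after cyclic loess between the arrays 1 was kept, the G1/S and DNA replication list (median -0.11, adjusted p = 0.0139, camera, within a range of 0.0003 to 0.669 over its alternatives). Of the 6 lost after cyclic loess (adjusted p = 0.0528 to 0.714), the medians were then -0.11 for P68 partners, -0.08 for oxidative phosphorylation, -0.06 for ribosome biogenesis, -0.05 for G2/M, -0.04 for ribosomal proteins and -0.03 for splicing. With the mean of a gene's probe sets the ribosomal protein median was -0.04 (adjusted p = 0.0395, camera).

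**Figure D3:**
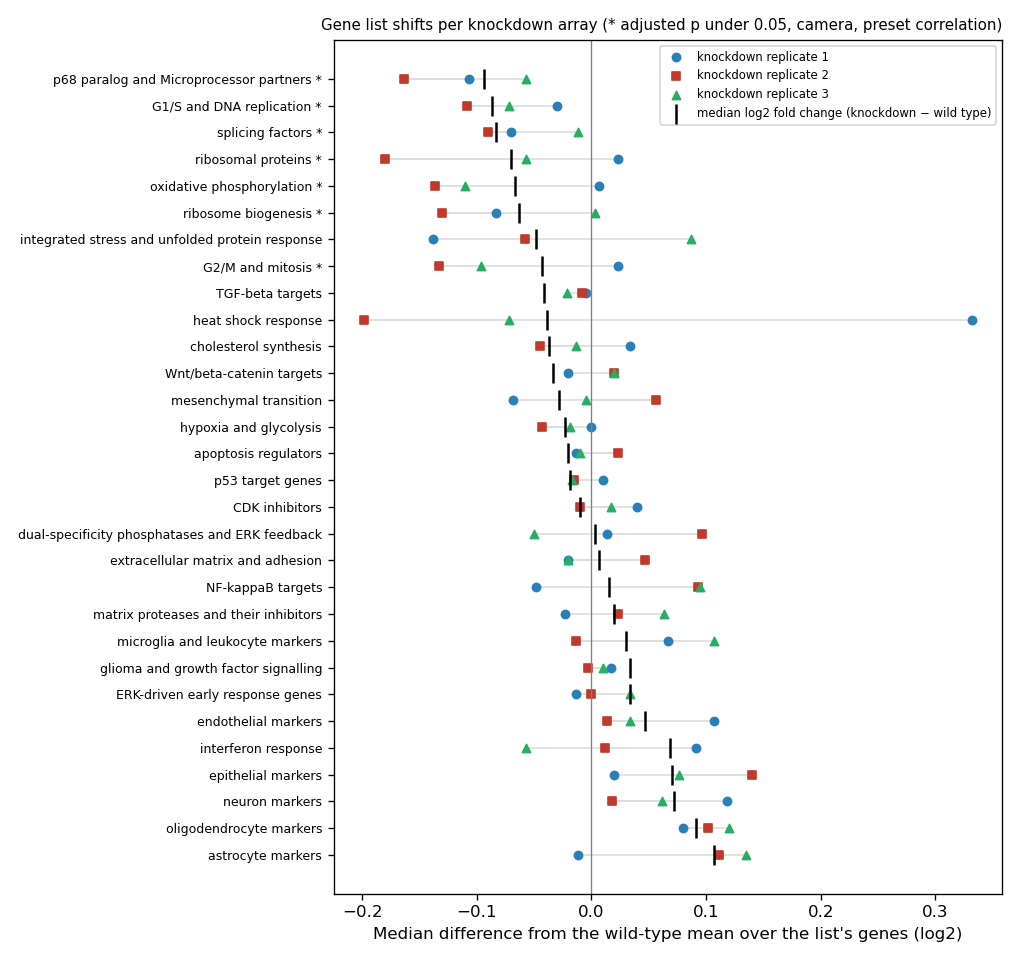
Median difference from the wild-type mean (log2, horizontal axis) over the genes of each list (vertical axis) on knockdown replicates 1, 2 and 3, with the list's median log2 fold change as a black bar and asterisks for adjusted p under 0.05 by camera with the preset correlation. The ribosomal protein list lies at 0.02, -0.18 and -0.06 in replicates 1, 2 and 3, and the heat shock list at 0.33, -0.20 and -0.07.

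Gene groups related to invasion did not pass the threshold. Of 27 matrix proteases and inhibitors, 15 lay above 0 (median 0.02, adjusted p = 0.727, camera). PLAU, the urokinase that converts plasminogen to plasmin, differed most, at 5.29 ± 0.07 in the knockdown and 5.03 ± 0.13 in the wild type (SD, n = 3 each). Of 34 extracellular matrix and adhesion genes, 19 lay above 0 and 14 below (median 0.01, or -0.004 after cyclic loess, with a downward camera test at an adjusted p of 0.935), and the matrix protein SPARC gave -0.46 ± 0.27 (log2 difference ± SE). Of 16 mesenchymal transition genes, 8 lay on each side of 0 (median -0.03, adjusted p = 0.727, camera), with the cadherin CDH11 at -0.39 ± 0.16 (SE). Among 20 TGF-beta target genes, 11 lay below 0 (median -0.04, adjusted p = 0.727, camera), with the SMAD corepressor SKIL at -0.23 ± 0.13 (SE). SPARC gave -0.115 without wild-type replicate 1, the brightest of the 6 arrays for it at 6.25, and -0.74 without wild-type replicate 3. CDH11 gave -0.26 without knockdown replicate 2 and -0.23 without wild-type replicate 1, and SKIL -0.135 without wild-type replicate 3. With single arrays left out the medians ran from -0.02 (without knockdown replicate 2) to 0.065 (without knockdown replicate 1) for the proteases, from -0.006 (without knockdown replicate 2) to 0.04 (without knockdown replicate 3) for the matrix list, from -0.06 (without knockdown replicate 2) to 0.05 (without wild-type replicate 3) for the mesenchymal list and from -0.04 (without wild-type replicate 3) to -0.005 (without wild-type replicate 2) for TGF-beta targets.

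Growth control and survival lists were likewise not past the threshold. The 5 measured CDK inhibitors had a median of -0.01 and a mean of 0.0007 (adjusted p = 0.935, camera; median 0.02 after cyclic loess), and CDKN2B differed most at 0.17 ± 0.12 (SE). Of 22 p53 target genes, 12 lay below 0 (median -0.02, adjusted p = 0.689, camera), with TP53INP1 at 5.59 ± 0.07 in the knockdown and 5.88 ± 0.07 in the wild type (SD, n = 3 each). Among 17 apoptosis regulators, 10 lay below 0 (median -0.02, mean 0.01, adjusted p = 0.851, camera), and the antiapoptotic BCL2L1 gave 0.33 ± 0.23 (SE). The 17 Wnt and beta-catenin targets had a median of -0.03 and a mean of 0.004 (adjusted p = 0.935, camera), with the transcription factor LEF1 at 0.25 ± 0.11 (SE). BCL2L1 gave 0.63 without wild-type replicate 1, 0.095 without wild-type replicate 3 and 0.21 without knockdown replicate 1, and CDKN2B gave 0.055 without knockdown replicate 2. All 4 medians turned sign with single arrays left out, to 0.055 for the CDK inhibitors (without knockdown replicate 3), 0.02 for p53 targets and 0.008 for apoptosis regulators (both without wild-type replicate 1) and 0.03 for Wnt targets (without knockdown replicate 2).

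HK2 and LIF passed the threshold over their list alone and not over all genes. Each of the 30 lists was adjusted on its own at 0.05, and 2 held a passing member. With that many lists, a few passing members would arise by chance if no gene differed. HK2, the hexokinase of the first step of glycolysis, was 5.43 ± 0.10 in the knockdown and 5.89 ± 0.10 in the wild type (SD, n = 3 each), a log2 difference of -0.46 ± 0.10 (SE) with a limma adjusted p of 0.0367 over the hypoxia and glycolysis list. LIF, a cytokine of the interleukin-6 family, was 3.68 ± 0.02 against 4.10 ± 0.10 (SD, n = 3 each), a log2 difference of -0.41 ± 0.10 (SE) with a limma adjusted p of 0.0428 over the NF-kappaB list. With any 1 of the 6 arrays left out, the value for HK2 lay between 0.0501 and 0.227. For LIF it was 0.0475 without wild-type replicate 1 and between 0.116 and 0.269 without any other array, and LIF also missed the threshold with every probe set tested (0.051) and with an intensity trend (0.0549). LIF was also among the dimmest 40% of genes by mean signal. The lists themselves did not pass the threshold. Of 30 hypoxia and glycolysis genes, 18 lay below 0 (median -0.02, adjusted p = 0.751, camera), and of 24 NF-kappaB targets, 13 lay above 0 (median 0.02, or -0.002 after cyclic loess, with a downward camera test at an adjusted p of 0.935). Leaving out wild-type replicate 1 turned these medians to 0.045 and -0.02.

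Stress and metabolic lists did not pass the threshold either. The 30 interferon response genes had a median of 0.07 (adjusted p = 0.935, camera), and IFI44L differed most at -0.29 ± 0.10 (SE), while the median was -0.03 without knockdown replicate 1 and 0.03 without knockdown replicate 2, and lay just below 0 without wild-type replicate 2. The 28 genes of the integrated stress and unfolded protein responses had a median of -0.05 (adjusted p = 0.321, camera), with VLDLR at -0.22 ± 0.13 (SE), and without wild-type replicate 1 the median was -0.16 (adjusted p = 0.0003, camera, the lowest of a range up to 0.995 over its alternatives) and without knockdown replicate 1 it was 0.03, with VLDLR at -0.08 without knockdown replicate 2 and -0.13 with array weights. The 14 heat shock genes had a median of -0.04 (adjusted p = 0.935, camera), with HSPA1L at 0.23 ± 0.12 (SE), and without knockdown replicate 1 the median was -0.14 (adjusted p = 0.0165, camera, the lowest of a range up to 0.995), with HSPA1L at 0.14, and without wild-type replicate 1 it was 0.09. The 18 cholesterol synthesis genes had a median of -0.04 (adjusted p = 0.727, camera), with INSIG1, which restrains sterol synthesis, at 0.15 ± 0.10 (SE), and without wild-type replicate 1 the median was 0.03.

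Markers of cell types, some of them glial like the studied glioma line, were compared as a check on the samples, and none of these 6 lists passed the threshold. The 10 oligodendrocyte markers had a median of 0.09 (adjusted p = 0.0638, camera), led by CNP at 6.48 ± 0.16 in the knockdown and 6.10 ± 0.10 in the wild type (SD, n = 3 each). The 12 astrocyte markers had a median of 0.11 (adjusted p = 0.209, camera), led by the water channel AQP4 at 0.37 ± 0.11 (SE). The 11 epithelial markers had a median of 0.07 (adjusted p = 0.176, camera), with the keratin KRT19 at 0.33 ± 0.11 (SE). The 14 neuron markers had a median of 0.07 (adjusted p = 0.321, camera), with STMN2 at 0.32 ± 0.11 (SE). The 13 microglia and leukocyte markers had a median of 0.03 (adjusted p = 0.499, camera), with the lysosomal protein CD68 at 0.50 ± 0.15 (SE). The 11 endothelial markers had a median of 0.05 (adjusted p = 0.758, camera), with CLDN5 at 0.27 ± 0.10 (SE). The neuron median was 0.002 with the dimmest 40% of genes left out or with the mean of a gene's probe sets. The microglia median was -0.008 and the astrocyte median 0.05 without knockdown replicate 3, and without wild-type replicate 1 the endothelial median was -0.015 and the epithelial median 0.13.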

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

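No gene passed the threshold under any of the 15 other settings of the limma fit, nor at an adjusted p under 0.01. DDX5 stayed lower and DUSP5 higher in each of these settings, between -0.58 and -0.36 and between 0.35 and 0.44 on the log2 scale, and their adjusted p over the 3 preset genes ranged from 0.00304 to 0.0278 and from 0.00525 to 0.0278. At an unadjusted p under 0.05, leaving out the dimmest 40% of genes gave 327 higher and 240 lower genes, and testing every probe set gave 829 higher and 688 lower, as fewer or more were tested. Leaving out single arrays gave 320 higher genes (without wild-type replicate 2) to 805 (without knockdown replicate 1), and 223 lower genes (without wild-type replicate 2) to 591 (without wild-type replicate 1). The lower lists numbered 0 with an estimated correlation, 4 without the dimmest 40% of genes, 1 after cyclic loess and 7 with the mean of a gene's probe sets, and leaving out single arrays gave 0 (without knockdown replicate 2) to 6 (without knockdown replicate 1), with 4 without wild-type replicate 1. Why calls ended with cyclic loess and without single arrays was not tested. No list was higher under any alternative. Arrays of the same replicate number deviated from their group means with correlations of 0.268, -0.0273 and 0.125 for numbers 1, 2 and 3, so the numbers were not taken to pair the arrays, although knockdown replicates 1 and 3 correlated best with the wild-type array of their number (r = 0.988 and 0.991) and only knockdown replicate 2 did not. An effect shared by the arrays numbered 1 was not excluded, and the main fit holds any such effect in its error. With the replicate number as a block, 0 genes passed, 626 were higher and 523 lower at an unadjusted p under 0.05, and 7 lists were lower, while HK2 and LIF had adjusted p = 0.057 and 0.067 over their list alone. Of 428 values of 29 genes named by the rule for lists, 0 changed sign under the alternatives but 21 values of 13 genes moved by over 1.5 times, and of 102 values of 7 genes chosen after their values were seen, 1 changed sign (MKI67) and 6 of 4 genes moved so far. The 29 genes were picked for the largest difference of their list in these data. Settings such as the replicate block and the intensity trend cannot change the difference itself, so the count of sign changes is a weak test. Signal over background was not used here, so what it limits was assessed only by leaving out the dimmest genes.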

Other observations

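The tests on a single knockdown array, on correlated genes within the 7 lists and on the label of knockdown replicate 3 were chosen only after values bearing on them were seen, the medians without knockdown replicate 2 and after cyclic loess were weighed only after they were seen, and the small nucleolar RNAs were picked as a class after the data were seen. Heat shock and stress genes differed between single arrays of both groups. The median of 14 heat shock genes lay at 0.33, -0.20 and -0.07 from the wild-type mean on knockdown replicates 1, 2 and 3, and at 0.14, -0.04 and -0.13 on wild-type replicates 1, 2 and 3. The median of 28 integrated stress and unfolded protein response genes lay at -0.14 on knockdown replicate 1, -0.06 on knockdown replicate 2 and 0.09 on knockdown replicate 3, and at -0.27, 0.10 and 0.13 on wild-type replicates 1, 2 and 3. In both lists the knockdown and wild-type arrays numbered 1 lay at the same end, highest for heat shock and lowest for the stress list. By class of RNA, 632 long non-coding RNAs had a median log2 difference of 0.06, with 50 higher and 7 lower at an unadjusted p under 0.05, against a median of 0.01 for 16902 protein-coding genes. Their medians from the wild-type mean were 0.01, 0.115 and 0.035 on knockdown replicates 1, 2 and 3. Without knockdown replicate 2 the median log2 difference was 0.03. As a class picked after the data were seen, they gave camera p = 0.000471 with the preset correlation and p = 0.161 with the estimated one. Of 9636 probe sets without a single gene symbol, 0 passed the threshold in limma, and 522 had an unadjusted p under 0.05 against 481.8 expected.

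DDX5 was number 33 and DUSP5 number 38 of the 18417 genes in order of p, where an even distribution of p-values would place 62.0 and 66.8 genes at values as small. Values of p as small as theirs were thus no more frequent in this fit than in data without any effect. The larger p-values were not evenly distributed. Bins of 0.05 held 941 to 1083 genes between 0.05 and 0.5 and 806 to 924 above 0.5, and limma estimated 96.0% of genes to be without a difference. Whether this unevenness reflects the groups was not tested. Both genes stand out only as genes chosen in advance, under an adjustment over 3 genes that was set after the data were seen.

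With 10 splits of the 6 arrays into 3 and 3, no share under 0.05 can be reached. For genes at an unadjusted p under 0.05, 5 of the 10 splits gave at least the 937 of the real split, which is included, and the highest other split gave 1713. For lists past the camera threshold, 4 of the 10 gave at least the 7 of the real split, and the highest other gave 9. The split with 1713 genes set knockdown replicates 1 and 2 and wild-type replicate 1 against the rest, which points to a structure of the arrays other than the groups. All 4 of the other splits with at least 937 genes held knockdown replicate 1 and wild-type replicate 1 on the same side. Of the splits that held these arrays apart, the real one gave the most genes and lists, and the next gave 785 genes and 5 lists. This subset was set after the counts were seen and drops every split that exceeded the real one in genes. The order within it is therefore no test of a group effect. The counts over all splits are thus mixed with that structure and cannot tell a group effect from it.

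The first pattern weighed is the 7 lists that lay lower in the knockdown. A dependence on a single knockdown array cannot be told apart from a shift of the lists. With 0 of the 7 calls left without replicate 2 and 5 left without replicate 1 or 3, the criterion for such a dependence was met. However, the median lost most of its size only for ribosomal proteins (-0.002 ± 0.03, SE). It stayed between -0.07 and -0.03 for the other 6, with ribosome biogenesis at -0.07 ± 0.04 (SE). Correlated genes within lists may account for the calls as well, but the test cannot decide it. With an estimated correlation 0 of the 7 calls were left, yet no list passed that setting in any of the 10 splits. Among lists with an estimated correlation below the preset 0.01, the oligodendrocyte markers had the smallest p. Their camera p still rose from 0.0170 to 0.0674 with the estimated correlation of -0.05, so that setting raised p for another reason than correlated genes. A brightness trend between arrays could cover part of the pattern. The medians of 4 of the 7 lists lay within the central 95% of 10000 random lists matched on mean signal. This met the criterion set for such a trend in advance. The G1/S and DNA replication, oxidative phosphorylation and ribosome biogenesis lists lay below that range (0.01%, 1.04% and 1.96% of random lists were as low). After cyclic loess the median was smaller by more than its standard error only for splicing (-0.03 ± 0.02, SE). The trend is left open only through these medians after cyclic loess, weighed after they were seen. These standard errors of the medians were taken over the genes of a list as if independent, not between arrays. With estimated correlations of 0.07 to 0.20 within the lists they are too small, so they cannot settle which medians changed. A response to lower P68 remains open and was not separated from knockdown replicate 2.

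The second pattern is that knockdown replicate 3 correlated more closely with each wild-type array (r = 0.987 to 0.991) than with the other two knockdown arrays (r = 0.985 and 0.986). Knockdown replicate 1 was similar, with r = 0.988, 0.983 and 0.985 to wild-type replicates 1, 2 and 3. Its r was 0.979 and 0.985 to knockdown replicates 2 and 3. The arrays thus did not separate by group, and the pattern is not particular to replicate 3. The median gene SD of 0.139 in the knockdown against 0.115 in the wild type, and the low array weights of knockdown replicates 1 and 2 (0.659 and 0.606), restate these correlations, so a wider spread among the knockdown arrays as their source was not tested. A mislabelled array cannot be told apart from a weaker knockdown. For 2 of 2 genes, DDX5 and DUSP5, replicate 3 lay inside the 95% prediction interval of a further wild-type array (9.67 to 10.76 and 4.93 to 5.76), yet nearer to the mean of the other knockdown arrays than to that of the wild type, and for DDX5 replicate 2 (9.79) lay inside it as well, so that only DUSP5 (5.78 and 5.80 on replicates 1 and 2) sets replicate 3 apart. A lower efficiency of the siRNA on that array was not tested.

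The third pattern is the small nucleolar RNAs, guides of RNA modification mostly processed from introns. Of 175, 114 lay below 0 with a median of -0.06, and SNORA23, chosen after its values were seen, gave 5.05 ± 0.12 in the knockdown and 5.59 ± 0.07 in the wild type (SD, n = 3 each). The median signal of the class was 3.03, below the lower quartile of all probe sets on every array (3.14 to 3.16). At such levels signal cannot be told from background here, and the class was not tested with dim genes left out. The values argue against a brightness trend shared by genes of such signal, since 0 percent of 10000 signal-matched random lists had a median as low. That percent overstates how rare the median is. The class was picked after the data were seen, and its genes were correlated while those of random lists were drawn without regard to correlation. No value after cyclic loess is given for the class. The part of a single knockdown array cannot be told apart from a shift of the class. Without replicate 1 the median was -0.11, and without replicate 2 it was -0.0383 (p = 0.0236, camera with the preset correlation). The latter lay within 0.0179 of -0.03, the bound set for it. This 0.0179 is the standard error of the median with all 6 arrays, not of the median without replicate 2. It was added to the rule after the median was seen. Whether correlated genes within the class account for the shift cannot be told. The camera test gave p = 4.62e-05 with the preset correlation and p = 0.119 with the estimated one. That setting also raised p for the oligodendrocyte markers, whose estimated correlation lay below the preset one. The standard error of the class median was likewise taken over genes as if independent, and with an estimated correlation of 0.06 it is too small.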
